A study of Rattus norvegicus with 8 samples.

How the data were processed

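Hippocampal RNA from 8 Sprague Dawley rats, 2 months old, was profiled with 1 array per animal, 4 control animals and 4 animals that had undergone early stress. Per the labels' protocols, litters were assigned at random to a group, and early stress meant separation of the pups from the dam for 3 hours a day from postnatal day 2 to postnatal day 14. Control litters were disturbed only by routine handling, and all litters were weaned on postnatal day 30. RNA was purified on columns, its quality was checked by capillary electrophoresis, and 500 ng was amplified from an oligo-dT primer and labelled with the dye Cy3, per the labels' protocols. The labelled RNA was hybridized to a custom rat array from Agilent in a 1-colour layout. Oligo-dT priming reads mainly polyadenylated transcripts.

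The values are log2 signals as deposited by the authors, rounded to 2 decimals. The log base and the scaling were read from the values: the 75th percentile was 0 on every array, and each array spanned 14.2 to 14.6 units. The values were not centred per probe, so that they keep the level of a probe as well as differences between arrays. The scanner software, the background correction, the normalization step and any filter on probes are not given in the sources used here, and neither are detection flags, slide, hybridization day, sex or the litter of each animal. Because each array was set to its 75th percentile, a difference between groups is relative to that level, and a shift of all transcripts together would not be seen. A dim signal meets a lower limit that lies at a different height on each array. This limit compresses differences between dim probes and can add a difference between arrays.

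The table held 14043 probes without missing values. Of these, 13908 had catalogue numbers and 135 had numbers of the custom design. The files do not pair probes with genes, and 0 probe numbers were found in the rat gene table at hand, so the probe was the unit of every test. The gene lists fixed in advance (stress hormone signalling, synaptic genes, cell types and others) were therefore not tested, and the genes to be named in any case could not be located.

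Differences were computed as early stress minus control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the sole term). P-values are two-sided and were adjusted by the Benjamini-Hochberg method over 14043 probes, with a threshold of 0.05. A second, descriptive set held the probes at an unadjusted p under 0.05 and a difference of at least 1.5-fold. Intervals are 95% confidence intervals from the same model. The test, the naming rule, both thresholds and most alternatives were fixed before the data were examined. By the naming rule, with no probe past the adjusted threshold, probes were taken in order of unadjusted p among those at p under 0.05, at least 1.5-fold, and without overlap between groups. As no gene names could be given, the first probe in each direction is printed, with the first in each direction among probes above the floor added after values had been seen.

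The floor of an array was taken as its lowest value, and a probe within 0.5 log2 units of it was counted as within the floor band. This definition was chosen after seeing the data. Where all 4 arrays of a group lay in the band, the fold is also given against the band: the mean of the brighter group was set against the mean, over the arrays of the dimmer group, of the upper edge of the band or the probe's own value, whichever was higher. This fold depends on the width of the band and is no lower bound. Summaries of each array were compared by exact two-sided permutation tests over 70 assignments, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over 4 measures. Principal components were computed from the probe-centred values.

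The procedure was tested on simulated data with the probe means and spreads of the 8 arrays and 200 changed probes among 14043. At an adjusted p under 0.05, it recovered 23.6% of probes changed 1.5-fold, 61.8% at 2-fold, 80.0% at 3-fold and 88.5% at 4-fold. Among the 12389 probes above the floor on all 8 arrays, the shares were 34.8%, 68.4%, 88.2% and 93.2%. All recovered probes had the simulated direction. The simulation drew independent normal noise for each probe, without a floor and without deviations shared between probes. In each run all 200 probes changed by the same fold. The shares therefore may not hold for the measured arrays.

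Alternatives covered quantile normalization, centring on the median, a shift to the 75th percentile, removal of the dimmest 25% of probes, a trended and robust variance model, array weights, the replicate number as a block, each array left out in turn, and other thresholds. Alternatives added after seeing the data were a restriction to probes above the floor, a common floor, cyclic loess, removal of 2 arrays together, and a covariate from the within-group deviations. No array was left out of the reported comparison. With 4 animals per group, the number of arrays limits the precision, and animals that share a litter would vary less than independent ones.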

Results

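The series asked how the early stress of maternal separation bears on the transcripts of the hippocampus in young adulthood. Maternal separation removes rat pups from the dam for part of each day during the first weeks of life and is a common model of early adversity. Hippocampal RNA was measured in 4 control rats and 4 rats separated as pups, with 1 array per animal and 14043 probes per array. The median log2 signal, relative to the 75th percentile of each array, was -2.34 ± 0.11 in control and -2.33 ± 0.05 in early stress (SD, n = 4 each; exact permutation p = 1).

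No transcript differed between early stress and control after correction for multiple testing. By limma, 0 of 14043 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.803. At an unadjusted p under 0.05 there were 767 probes (5.46%), with 460 higher and 307 lower in early stress. A share of 0.05 would be 702 probes. Of the 35 splits of the 8 arrays into 4 and 4, 8 gave a count as large as 767, the real split included. Most differences were small, with a median size of 0.11 on the log2 scale and a median standard error of 0.15. The 95% confidence interval lay within 1.5-fold in either direction for 8576 probes (61.1%) and within 2-fold for 11670 (83.1%), so that for most probes a change larger than 2-fold was outside the interval. Of the 11670, 591 were within the floor band on at least 1 array, where a narrow interval may reflect the floor and does not exclude a change of the transcript. With each array left out in turn, the count of 767 ran from 447 (without early stress replicate 3) to 1092 (without control replicate 4). It was 471 without control replicate 3, where 1 probe, A_43_P15375, had an adjusted p of 0.0375 by limma. Without control replicate 2 the count was 908, with a smallest adjusted p of 0.0553 by limma. The count was 1335 with array weights, 487 with the trended and robust variance model and 329 without the dimmest 25% of probes.

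**Figure D1:**
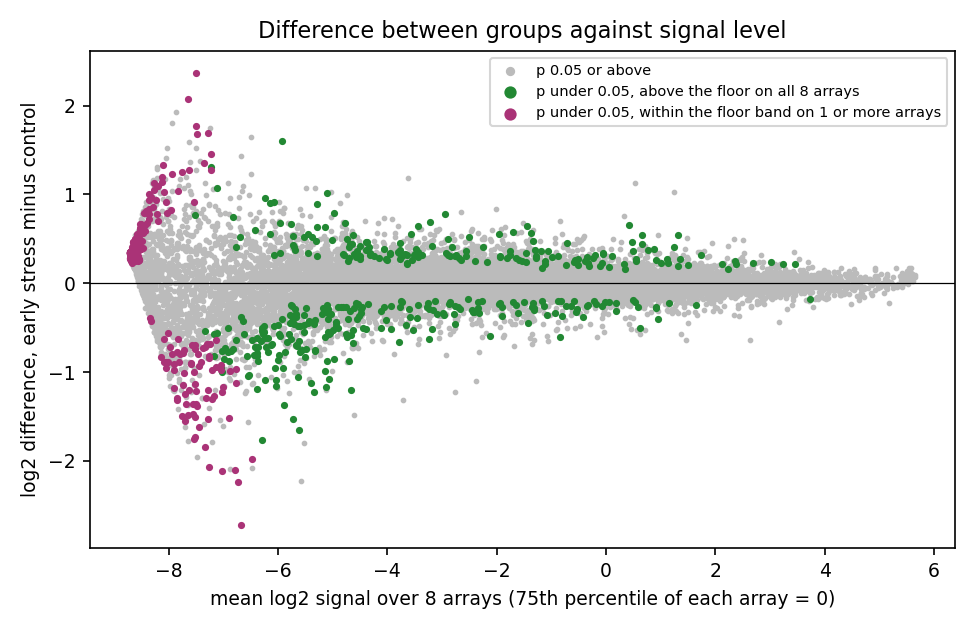
Log2 difference between early stress and control (vertical axis) against the mean log2 signal over the 8 arrays (horizontal axis, 75th percentile of each array at 0), 1 point per probe. Of the 767 coloured probes at an unadjusted p under 0.05, 399 lay above the floor on all 8 arrays (green) and 368 lay within 0.5 log2 units of the lowest value on at least 1 array (purple).

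A difference of at least 1.5-fold together with an unadjusted p under 0.05 was found for 214 probes, 68 higher and 146 lower in early stress. After quantile normalization the set held 153 probes, 70 higher and 83 lower, so that the share of higher probes went from 31.8% to 45.8%, and with values raised to a common floor it held 21 higher and 104 lower (16.8% higher). The number of higher probes was 42 without control replicate 3, 44 without control replicate 2 and 103 without early stress replicate 1. Both groups were fully separated, with no overlap between the 4 arrays of each, for 583 probes (4.15%), where chance gives 2.86%. Among the 12389 probes above the floor on all 8 arrays this share was 2.39% (296 probes), and among the 254 within the floor band on all 8 arrays it was 65.7%. How far the share varies between splits of the arrays was not computed. The set lay largely among dim probes. Of the 214 probes, 121 (56.5%) were within the floor band on at least 1 array, and 16 probes passed both criteria when the dimmest 25% of probes was left out. With array weights the set held 394 probes, 84 higher and 310 lower.

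The first probes by the naming rule are given as values, since none passed the adjusted threshold. A_43_P20604 had a log2 signal of -7.00 ± 0.39 in control and -8.50 ± 0.17 in early stress (SD, n = 4 each). All 4 early stress arrays were within the floor band, and against the upper edge of the band the signal was 2.13-fold lower there. The measured difference was -1.50 (SE 0.20; 95% confidence interval -1.95 to -1.05), with an unadjusted p of 6.61e-05 and an adjusted p of 0.803 by limma, and with values raised to a common floor it was -0.93. A_43_P11916 had -8.69 ± 0.28 in control, where all 4 arrays were within the floor band, and -6.33 ± 0.85 in early stress (SD, n = 4 each). Against the upper edge of the band or the probe's own value it was 4.19-fold higher in early stress, with a measured difference of 2.36 (SE 0.39; interval 1.45 to 3.27), an unadjusted p of 0.000354 and an adjusted p of 0.861 by limma. With values raised to a common floor the difference was 1.61.

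Among probes above the floor on all 8 arrays, the first in each direction were chosen after their values were seen. A_44_P410670 had -4.30 ± 0.23 in control and -4.97 ± 0.04 in early stress (SD, n = 4 each). Its difference of -0.67 (SE 0.12; interval -0.95 to -0.39) is a 1.59-fold lower signal in early stress, with an adjusted p of 0.861 by limma. A_44_P384286 had -7.88 ± 0.42 in control and -6.57 ± 0.50 in early stress (SD, n = 4 each), a 2.47-fold higher signal. Its difference was 1.31 (SE 0.29; interval 0.63 to 1.98), also with an adjusted p of 0.861 by limma. This probe was close to the floor in control. Control replicates 2 and 4, at -8.23 and -8.25, lay just above the band of arrays whose lowest values were -8.83 and -8.80. With values raised to a common floor the difference was 1.15.

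**Figure D2:**
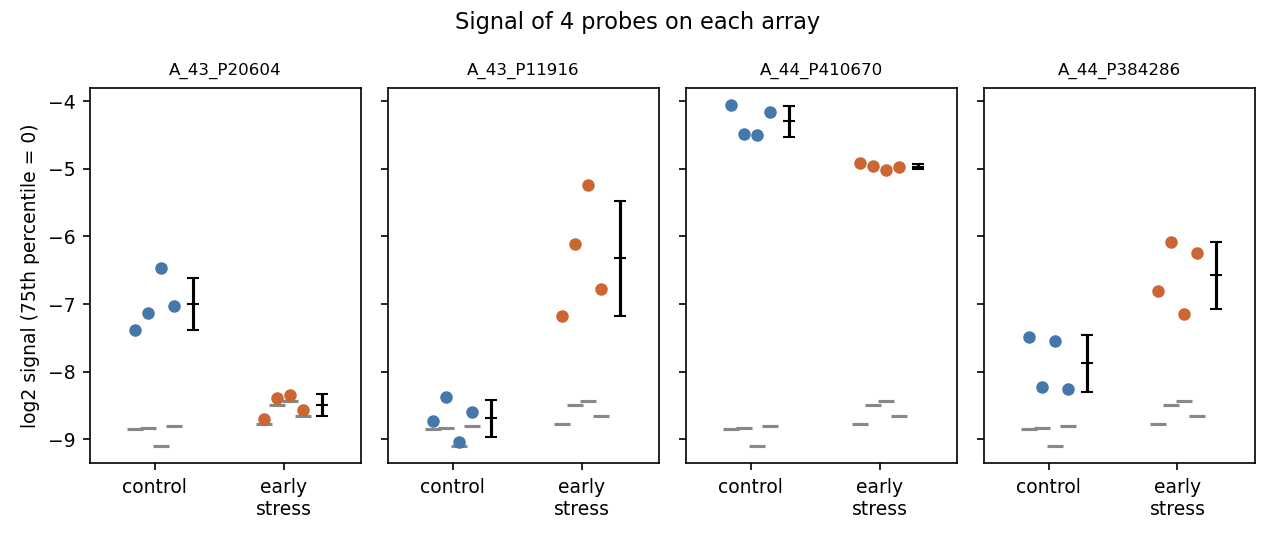
Log2 signal (75th percentile of each array at 0) of 4 probes in control (blue) and early stress (orange), 1 point per animal, with black bars for the mean ± SD and grey dashes for the lowest value of each array. The early stress arrays of A_43_P20604 and the control arrays of A_43_P11916 lie within 0.5 log2 units of the grey dashes, while both groups of A_44_P410670 lie above them. Control replicates 2 and 4 of A_44_P384286 lie just beyond 0.5 log2 units from the dashes.

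The comparison was repeated by signal level. Among the 12389 probes above the floor on all 8 arrays, 399 (3.22%) had an unadjusted p under 0.05, with 170 higher and 229 lower in early stress. A share of 0.05 would be 619 probes. Fitted alone, the 12389 probes gave 440. Of the 35 splits of the 8 arrays into 4 and 4, 16 gave a count as large, the real split included. The set at 1.5-fold or more held 93 of the 399, 22 higher and 71 lower. For these 12389 probes the 95% confidence interval lay within 2-fold for 11079 (89.4%). Of the 1654 probes within the floor band on at least 1 array, 368 (22.2%) had an unadjusted p under 0.05, 290 higher and 78 lower. The 254 probes within the band on all 8 arrays held 222 at this level, all of them higher in early stress, with a median log2 difference of 0.32. Adjusted over these 254 probes alone, a set defined from the measured values, 216 had an adjusted p under 0.05 by limma (smallest 0.0391). Membership holds each value within 0.5 log2 units of its array's lowest value, which itself was 0.305 higher in early stress. The size and direction of the differences in this set are therefore tied to the floor, and the 254 probes are not independent tests. Adjusted in the same way, 2 of the 110 probes within the band on all control arrays only (A_43_P11916 and A_43_P15811, both higher) and 1 of the 335 within the band on all early stress arrays only (A_43_P20604, lower) passed, in sets whose membership depends on the difference between groups. Among the 12389 probes above the floor, adjusted over these alone, 0 passed.

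The probes were also ordered by mean signal and divided into 10 equal bins. In the dimmest bin, 287 were higher and 50 lower in early stress at an unadjusted p under 0.05, which is 62.4% of all higher probes. Bins 2 and 3 together held 52 higher and 168 lower, and bins 4 to 10 held 121 higher and 89 lower. After quantile normalization the dimmest bin held 64 higher and 42 lower. Over all probes the split of 460 higher and 307 lower became 312 and 249 after quantile normalization and 243 and 376 when all values were raised to a common floor, where the balance turned.

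**Figure D3:**
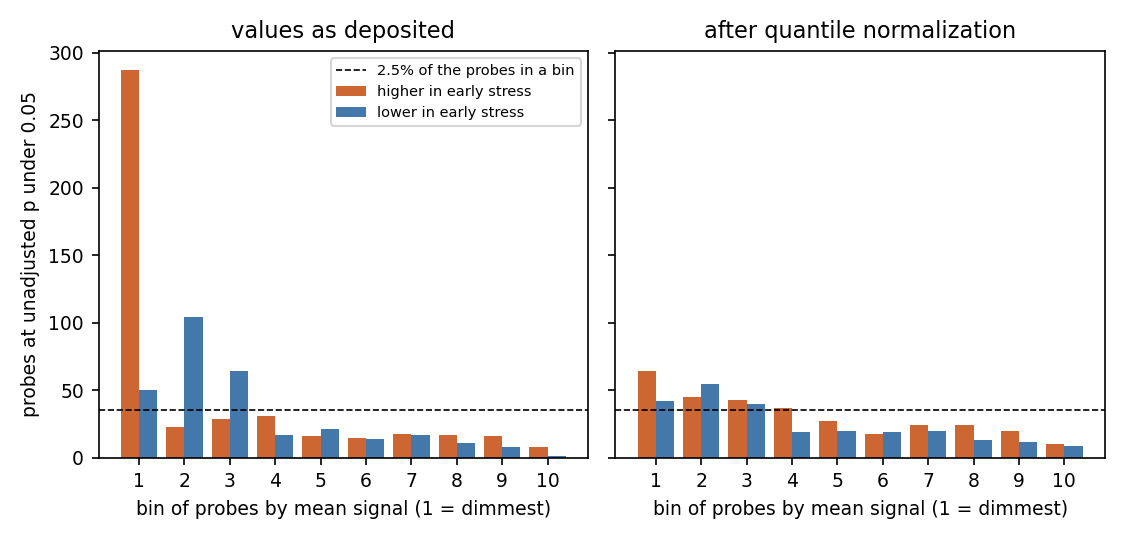
Number of probes at an unadjusted p under 0.05 (vertical axis) in each of 10 equal bins of the probes by mean signal (horizontal axis, 1 the dimmest), higher (orange) and lower (blue) in early stress, for the deposited values (left) and after quantile normalization (right), with a dashed line at the number chance gives per direction. The dimmest bin holds 287 higher probes in the deposited values and 64 after quantile normalization.

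The floor itself differed between the groups in level. The lowest value of an array was -8.89 ± 0.14 in control and -8.59 ± 0.16 in early stress (SD, n = 4 each), a difference of 0.31 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0572 over 4 measures), and the 4 lowest values were those of the 4 control arrays. The share of probes within the floor band was 6.0% ± 0.90 in control and 7.87% ± 0.42 in early stress (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0572). The 10th percentile was -7.19 ± 0.17 in control and -7.40 ± 0.08 in early stress (SD, n = 4 each; exact permutation p = 0.0571, adjusted p = 0.0761). None of these differences passed the adjusted threshold.

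Arrays of the same group were no closer to each other than arrays of different groups. Correlations across probes, which are not independent replicates, ran from 0.977 to 0.990 within groups and from 0.978 to 0.991 between groups. The median SD of the difference between a pair of arrays, over probes above the floor, was 0.47 within groups and 0.47 between groups. The first principal component took 27.9% of the variance and the second 23.9%, and neither separated the groups (exact permutation p = 0.486 and 0.886). Control replicate 4 and early stress replicate 3 stood apart on the first component, at 41.1 and 41.0, with the other 6 arrays between -24.0 and -0.50. Control replicate 2 stood apart on the second, at 51.6. With both arrays that stood apart on the first component left out, 0 probes had an adjusted p under 0.05 by limma, 557 had an unadjusted p under 0.05, and the 1.5-fold set held 247, 90 higher and 157 lower. The component that differed most between groups was the fourth, with 11.6% of the variance (exact permutation p = 0.0286, adjusted p = 0.2 over 7 components). As 0.0286 is the smallest possible p, a single component could not have passed this adjustment.

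**Figure D4:**
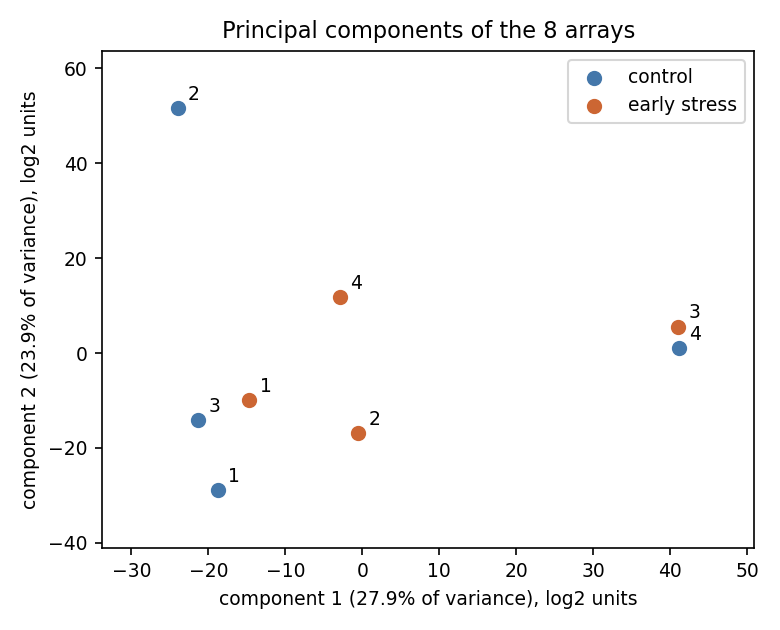
First (horizontal axis, 27.9% of the variance) and second (vertical axis, 23.9%) principal component scores in log2 units of the 8 arrays, 1 point per array, control in blue and early stress in orange, with replicate numbers. Control replicate 4 and early stress replicate 3 lie together at 41.1 and 41.0 on the first component, and control replicate 2 lies at 51.6 on the second.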

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

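The test of the array floor and that of weakly expressed transcripts were chosen only after the result was seen. The lowest value on control replicate 3, -9.10, lay apart from those of the other control arrays, at -8.84 to -8.80. Its gap to the nearest was 0.867 of the range of the group. Among 24 groups of values examined in this way, chance marks about 1 in 20.

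The dimmest of 10 equal bins of probes by mean signal held 287 that were higher in early stress at an unadjusted p under 0.05. In 1 of the 35 splits of the 8 arrays, the real one, as many went in a single direction (highest other 283). This share of 0.0286 is the smallest possible, and it became 0.2 after adjustment over 7 tests of splits. A single smallest share could not go below 0.2 there, so the adjustment could not have been passed. Chance cannot be excluded for the excess of higher probes in this bin. A floor moved by the scaling may give this pattern, since the lowest values differed by 0.31 and the floor probes by a median of 0.32, but the shift of each array to the same lowest value, after which the bin held 9 higher and 134 lower probes, would remove small rises of any origin. For a rise of weakly expressed transcripts, the dimmest 25% of probes above the floor on all 8 arrays were examined. Their median difference was -0.0775 (32 higher, 113 lower), but this filter drops transcripts rising out of the control floor. Among the 110 probes within the band on all control arrays only, the median was 0.676 (49 higher, 0 lower). Among the 335 within the band on all early stress arrays only, it was -0.183 (1 higher, 20 lower). Membership of these sets depends on the difference between groups, so their directions do not decide the question. The 10th percentile of each array involves no such choice of probes. Its mean was -7.19 in control and -7.40 in early stress, so signal at that level was not higher in early stress. This difference did not pass the adjusted threshold. For probes at the floor, the moved floor and a rise cannot be told apart, because such probes hold no level of their own.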

How the results depend on the processing

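The tests of probes above the floor, the common floor, cyclic loess, removal of 2 arrays and the covariate were chosen only after seeing the data. The count of probes with an adjusted p under 0.05 was 0 in 21 of 22 alternatives, which do not include adjustment within sets of probes at the floor. The shift to the 75th percentile and the requirement of a value on all 8 arrays left the data unchanged, so their counts of 0 are no test. With each array left out in turn the count ran from 0 to 1. The exception was the fit without control replicate 3, where A_43_P15375, chosen after its values were seen, had a difference of -2.54 and an adjusted p of 0.0375 by limma. The 1.5-fold set of 214 probes ran from 160 to 308 with each array left out. It held 16 probes without the dimmest 25% of probes (14 shared with the 214), 394 with array weights (172 shared), 95 among probes above the floor (93 shared), 125 with a common floor (123 shared), 79 at 2-fold and 767 without a fold threshold. The smaller sets follow from fewer or flattened dim probes or a stricter threshold. For array weights, and for the fit without control replicate 3, the cause was not tested. Lower probes outnumbered higher ones in the 1.5-fold set under every alternative that kept a fold threshold, but by margins that varied. The share of higher probes ran from 16.8% with a common floor to 45.8% after quantile normalization (70 higher, 83 lower). It was 43.8% without the dimmest 25% of probes (7 higher, 9 lower). These alternatives reuse the same arrays, and the direction of the set was not compared across splits of the arrays. The 4 named probes kept their direction under all of the 18 to 20 alternatives that tested them. Their differences ran from -1.76 to -0.93 for A_43_P20604, 1.61 to 2.64 for A_43_P11916, -0.74 to -0.59 for A_44_P410670 and 1.04 to 1.5 for A_44_P384286. These probes were picked from the same arrays without overlap between groups, so leaving out or weighting arrays could not reverse a direction. The replicate block, the trended and robust variance model and the covariate left each difference unchanged. For all these alternatives the kept direction is therefore no test.

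With the replicate block, 0 probes had an adjusted p under 0.05, 542 an unadjusted p under 0.05, and the 1.5-fold set held 232. Same-numbered arrays had deviation correlations across probes of 0.26, -0.0764, -0.292 and -0.135, and 2 of 8 arrays correlated best with their own number, so the numbers were not taken to pair the animals. A shift to the 75th percentile moved nothing, as the values already had it at 0. The gene list alternatives and the averaging of probes per gene were not run, as probes had no gene names. Signal near the floor limits the 1654 probes within the band on at least 1 array. The floor can compress their differences, and its own difference between the groups can add to them. The median size of the difference was 0.339 for these probes and 0.0975 for probes above the floor on all 8 arrays.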

Other observations

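The tests of the adjusted count, of dim-probe noise and of RNA from another tissue were chosen only after the result was seen. Of the 135 probes with custom numbers, 14 (10.4%) had an unadjusted p under 0.05, 13 higher and 1 lower in early stress, with a median difference of 0.04 over all 135. Of the 13 higher ones, 9 were within the floor band on all 8 arrays and 3 were above the floor on all 8.

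For probes with an adjusted p under 0.05 the real count was 0 (highest other 171), which 35 of 35 splits of the 8 arrays into 4 and 4 reach by definition, so the splits say nothing about it. For other counts, chance cannot be excluded. The 1.5-fold set was as large in 14 of 35 splits (real 214, highest other 761), and the count at an unadjusted p under 0.05 in 8 of 35 (real 767, highest other 2923). Among probes above the floor the latter count was as large in 16 of 35 (real 440 when fitted alone, highest other 2937). The split with 171, 761, 2923 and 2937 set control replicates 1 and 3 and early stress replicates 1 and 2 against the other 4 arrays. This split was picked as the highest after its counts were seen, and how high such a maximum runs by chance was not computed. Whether the counts come from a structure of the samples that the group labels do not give was therefore not tested.

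Early stress as a factor that sets the arrays apart was tested by the ratio of mean distance between groups to that within groups, which was 0.966 above the floor. In 24 of 35 splits the ratio was as large (highest other 1.17), so the arrays were not set apart by group on this measure. A change in the spread between animals was tested by the median log2 ratio of SDs, -0.37 for early stress over control. In 16 of 35 splits it lay as far from 0 (highest other 0.601 in size), so chance cannot be excluded there either.

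Control replicate 4 and early stress replicate 3 deviated from their group means together. Over probes above the floor their deviations correlated across probes at 0.592, which argues against noise of dim probes, and at 0.595 after cyclic loess, which argues against a scale difference that depends on signal. Without the probes set at least 4-fold apart, described below, the correlation was 0.488. Other pairs of arrays from different groups had deviation correlations from -0.516 to 0.371. A single hybridization listed under both labels is argued against by the SD of the difference between control replicate 4 and early stress replicate 3, 1.18 times that of the closest other pair (0.33 against 0.28). Of 895 probes at least 0.3 from the group mean on both arrays, 780 moved the same way (391 up, 389 down). Independent deviations would move the same way about as often as opposite ways. They would leave 305 probes at that distance on both arrays if all probes varied alike. Probes that vary more than others would raise that number, so it is no firm reference for the 895. What the shared deviations come from stays open, and no biological explanation was tested, since the labels give no factor that these animals share.

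Control replicate 4 and early stress replicate 3 had 27 probes at least 4-fold higher on both than on any other array, 14 of them at least 16-fold, and among all 28 pairs of arrays the highest count for any other pair was 3 (median 0). A set of 14 probes, of which 2 (A_42_P774782 and A_44_P449938, named after their values were seen) were among the 27, was at least 4-fold higher on control replicate 4 and early stress replicates 2 and 3 than on the other arrays, where no other triple of arrays had more than 1. RNA of another tissue might add transcripts in this way, but it was not decided: 1 probe, A_43_P11794, was at least 4-fold lower on both arrays, and as the other 27 pairs had 0, a low number of such probes does not single out this pair. The widest gap, chosen after its values were seen, was that of A_42_P575104, at 2.56 and 3.55 against at most -6.06 on the other 6 arrays. The smallest unadjusted p for early stress against control among the 27 was 0.652 by limma. Choosing probes that are high on 1 array of each group makes such a p large, so it says nothing about early stress. Neither a tissue, for want of gene names, nor genetic differences between the animals were tested.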
